A study of Homo sapiens with 6 samples.

How the data were processed

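The data were RNA sequencing counts of 6 libraries of cultured primary human pulmonary artery smooth muscle cells, 3 transfected with an empty vector and 3 with an SPHK1 plasmid. Per the labels' protocols, 300000 cells were plated in a growth medium for smooth muscle cells with serum, transfected with the reagent Xfect, given fresh medium after 4 h and collected after 48 h. Libraries were made from total RNA with the KAPA mRNA HyperPrep kit, per the labels' protocols. Groups were taken from the sample titles.

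The authors deposited 1 table with a row per gene. It holds whole-number read counts per gene and library, which the authors did not normalise, and log2 FPKM values, which are the authors' counts scaled to length and depth. It also holds the authors' own comparison as a fold change, a log2 fold change, a p-value and an adjusted p-value, and the gene's length, exons and coordinates. The submitters' processing notes name the genome build hg38 and the tools STAR 2.5, featureCounts 1.5.1, edgeR 3.22.5, MultiQC 0.11.5, FastQC and Subread, without saying what each did. The gene annotation, the strand setting of the counting, the treatment of reads that map to several places and the test behind the authors' p-values are not given in the sources used here. Every gene of the deposited table had at least 15 counts in some library, so the authors had removed genes of low counts. As the cells came from a human donor, genes of the Y chromosome and the X inactivation genes were removed before any step.

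All tests were run on the deposited counts. Libraries were scaled by edgeR's trimmed mean of M-values, and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation of dispersions, compared the groups in 2-sided tests with the group as the single term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The filter filterByExpr, at its defaults, removed 0 further genes. The common biological coefficient of variation was 0.0550. Levels are CPM, counts divided by the scaled library size, log2 fold changes have a standard error from the fit, and means are given with the SD of 3 libraries. Log2 CPM were computed with a prior count of 2. Intervals and errors from the counts carry the limit that reads without molecular identifiers are not independent molecules.

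Before the data were examined, 32 gene lists with 799 distinct genes were fixed, for pathways that the treatment could touch and for markers of other cell types. Members were matched by symbol or older symbol. The list of mitochondrially encoded genes had 0 measured members under the names used and gave no result. Each list was tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, SPHK1 left out and Benjamini-Hochberg adjustment over the 31 remaining lists. Camera was repeated with the correlation estimated from the data, and fry tested whether a list's genes move one way on balance or change in either direction. With an estimated correlation camera also takes its degrees of freedom from the libraries, not the genes. With few libraries this alone raises its p-values. Adjustment over the list alone means Benjamini-Hochberg adjustment of edgeR's p-values within that list.

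The genes named in the text were chosen by a rule fixed before the data were examined. It takes SPHK1, then the 12 largest rises and the 12 largest falls among changed genes with a mean log2 CPM of at least 1 whose groups do not overlap, and for each list up to 4 changed members with the smallest p, or the 2 with the smallest p as values where fewer changed. Genes named outside the rule are said to be so.

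Depth was 26691545 to 31979298 counts per library. On simulated counts with the libraries' own sizes and spread, in which 200 of 13273 genes were changed, the test recovered 64.9% of genes changed 1.3-fold, 76.1% of those changed 1.5-fold and 95.8% of those changed 2-fold, and 11 of 171 calls were false. In the simulated set test a list of 30 genes moved 1.1-fold was called, and 0 of 32 unmoved lists were. The simulated genes varied independently of each other, so false calls among correlated genes were not tested. In the measured data the estimated correlation was 0.794 in the list of interferon-stimulated genes. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 4.25 in each pair, so no library was counted as a copy of another. Pearson's r of log2 CPM, across genes, was 0.994 to 0.996 within groups and 0.992 to 0.995 between groups. The first principal component held 31.7% of the variance and separated the groups. By chi-square per degree of freedom, control replicate 2 was nearer to SPHK1 replicates 1 and 2 than to the other controls. It stood at 6.11 and 6.44 against these SPHK1 libraries, 7.34 and 8.185 against control replicates 1 and 3, and 14.3 against SPHK1 replicate 3. Other measures differed. Its highest Pearson's r was with control replicate 3, at 0.99511, against 0.99484 and 0.99402 with SPHK1 replicates 1 and 2 and 0.99397 with control replicate 1. On the first principal component control replicate 2 stood at -9.44, and control replicate 1, at -3.44, was the control nearest to the SPHK1 libraries.

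Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, stricter thresholds, the replicate numbers as a block and leaving out each library in turn. Alternatives added after seeing the data were the newer form of edgeR's quasi-likelihood test, edgeR's exact test, and offsets that remove each library's trend with GC content and gene length. GC content came from GENCODE 29 transcripts, and 97.2% of tested genes had a value.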

Results

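RNA sequencing was carried out on cultured human pulmonary artery smooth muscle cells, the contractile cells of the vessel wall that carries blood from the heart to the lungs. The cells were primary cells from a commercial supplier. They had been transfected either with an empty vector, the control group, or with a plasmid meant to over-express SPHK1, sphingosine kinase 1, the enzyme that phosphorylates the membrane lipid sphingosine to the signalling lipid sphingosine 1-phosphate (S1P). Each group held 3 libraries, from cells collected 48 h after transfection. The table gave 13273 genes to the tests. Total counts were 26998726, 28830913 and 31979298 in control replicates 1 to 3, and 29523008, 26691545 and 29732987 in SPHK1 replicates 1 to 3. Levels are given as CPM, counts scaled to libraries of equal effective size. The 10 most abundant genes, led by the matrix genes FN1, COL1A2, COL1A1 and COL3A1, took 17.2% to 18.3% of the counts of a library. Nothing in the labels says that the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

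The comparison asked how the transcriptome of these cells changes when SPHK1 is over-expressed. SPHK1 mRNA itself was 1.58-fold higher with the plasmid, and DIO2, a gene of thyroid hormone activation, and PTHLH, STC1, MMP1 and IL6, genes of secreted proteins, rose between 1.65-fold and 2.05-fold. All 53 measured genes of the interferon response had positive fold changes, and 15 of them passed the test. All 29 measured ribosomal protein genes had negative fold changes, and 13 of them passed. Within each of these lists the genes varied together, with an estimated correlation of 0.794 in the interferon list and 0.7585 in the ribosomal protein list. Their shared signs are therefore not separate pieces of evidence. Of 21 measured contractile genes, ACTA2, TAGLN and SYNPO2 fell and 18 did not pass. BMP4 and the alcohol dehydrogenase gene ADH1B also fell. In all, 293 genes changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 184 higher and 109 lower with SPHK1, and 1840 genes had an unadjusted p under 0.05. The share of changed genes that rose was 62.8%, and it was 52.6% when libraries were scaled by their total counts alone.

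The SPHK1 gene, on chromosome 17 at 76382977 to 76387860 of the human genome build hg38, had 174, 253 and 229 counts in the control libraries and 348, 336 and 322 in the SPHK1 libraries. Its level was 7.44 ± 1.17 CPM (SD, n = 3) in controls and 11.8 ± 0.850 CPM (SD, n = 3) with the plasmid. The log2 fold change was 0.66 ± 0.11 (SE), with an adjusted p of 0.00286 in edgeR's test. All 3 SPHK1 libraries lay above all 3 controls, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. SPHK1 ranked 100 among the tested genes by fold change and 37 by p. The table counts reads per gene, so it does not separate transcripts of the plasmid from those of the cells' own gene.

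**Figure D1:**
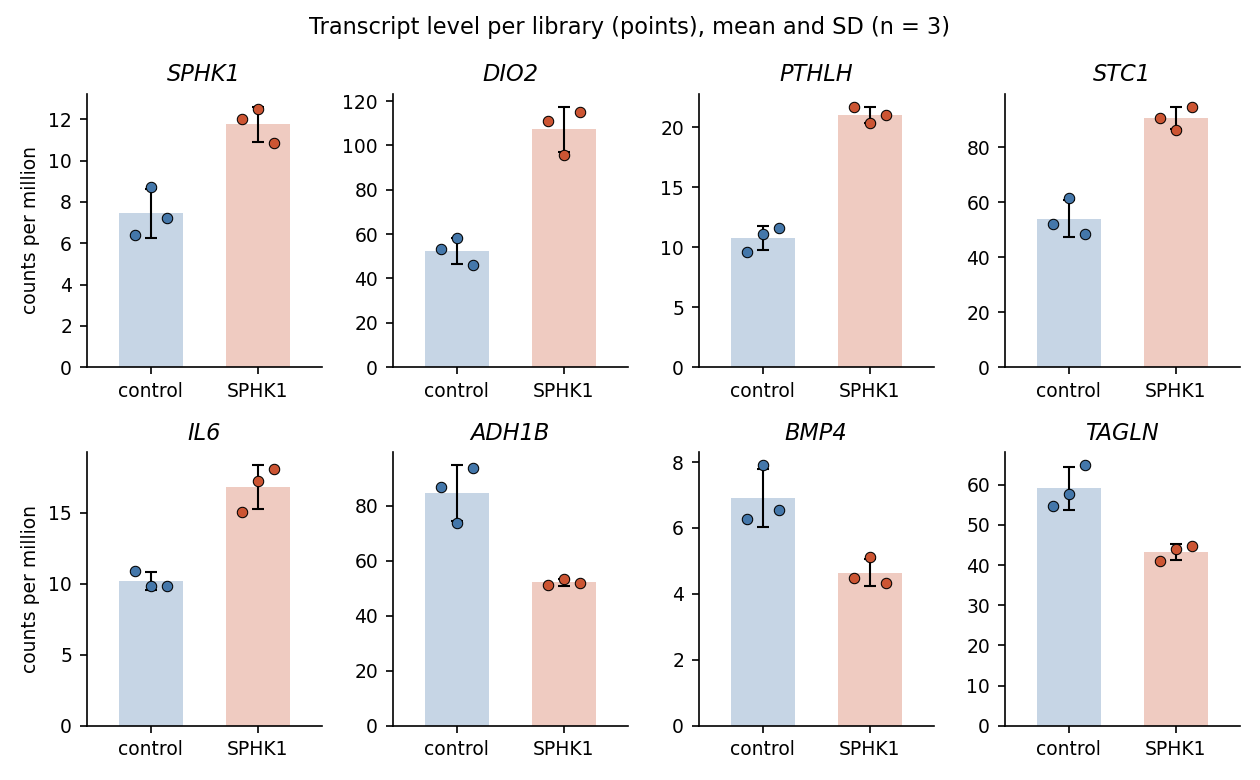
CPM (vertical axes, starting at 0) of 8 genes in the control and SPHK1 libraries, with points for single libraries, bars for means and error bars for the SD of 3 libraries. SPHK1 lay between 6.39 and 8.70 in controls and between 10.8 and 12.5 with the plasmid, and in each of the 8 genes the groups did not overlap.

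Among changed genes with a mean log2 CPM of at least 1, DIO2, which encodes the deiodinase that activates thyroid hormone, had the largest rise, from 52.4 ± 6.07 to 107 ± 10.3 CPM (SD, n = 3). PTHLH, the gene of parathyroid hormone-related protein, rose 1.95-fold, BMP6, a bone morphogenetic protein, rose 1.79-fold, and PENK and TRH, which encode neuropeptide precursors, each rose 1.69-fold. STC1, the gene of the glycoprotein hormone stanniocalcin 1, and MMP1, an interstitial collagenase, each rose 1.68-fold, and IL18BP, which encodes a soluble inhibitor of interleukin 18, rose 1.83-fold. The other large rises were those of GCA, a calcium-binding protein gene (1.95-fold), CTSS, the gene of the protease cathepsin S (1.79-fold), USP18, a deconjugating enzyme of ISG15 (1.74-fold), and HLA-F, a class I antigen gene (1.72-fold). GCA, CTSS, BMP6 and HLA-F were scarce, with 1.37 to 2.49 CPM in controls. BMP6 shares positions with TXNDC5, IL18BP with NUMA1, and HLA-F with related HLA genes, so reads may be split between them.

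By at least 1.5-fold, 27 genes rose and 2 fell. COPG2IT1, an RNA transcribed within COPG2, fell by 0.84 on the log2 scale, and its counts cannot be separated from those of COPG2 because the strand setting of the counting was not given in the sources used here. ADH1B fell from 84.7 ± 10.1 to 52.1 ± 1.19 CPM (SD, n = 3), and BMP4, another bone morphogenetic protein gene, from 6.91 ± 0.877 to 4.65 ± 0.421 (SD, n = 3). TAGLN, which encodes the actin-binding protein transgelin of smooth muscle, had a log2 fold change of -0.45 ± 0.06 (SE), and it shares positions with PCSK7. PINK1-AS, an antisense RNA of PINK1, fell by 0.43 on the log2 scale, G0S2, an inhibitor of fat breakdown, fell by 0.42 and ADGRD1, an adhesion receptor gene, fell by 0.40. RPSA and EEF2, genes of the translation machinery, and PALM, a membrane protein gene, each fell by 0.39, and the cadherin gene CDH13 and FLRT2 each fell by 0.38. PINK1-AS overlaps PINK1 and DDOST and has the same limit of strand. The groups did not overlap in any of the 293 changed genes. For changed genes this was nearly fixed in advance by the test. Over all tested genes they did not overlap in 2438, or 18.4%, where chance gives 10% on average. Genes vary together, so the share in a single split can lie far from 10%, and 18.4% is no test of the groups.

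**Figure D2:**
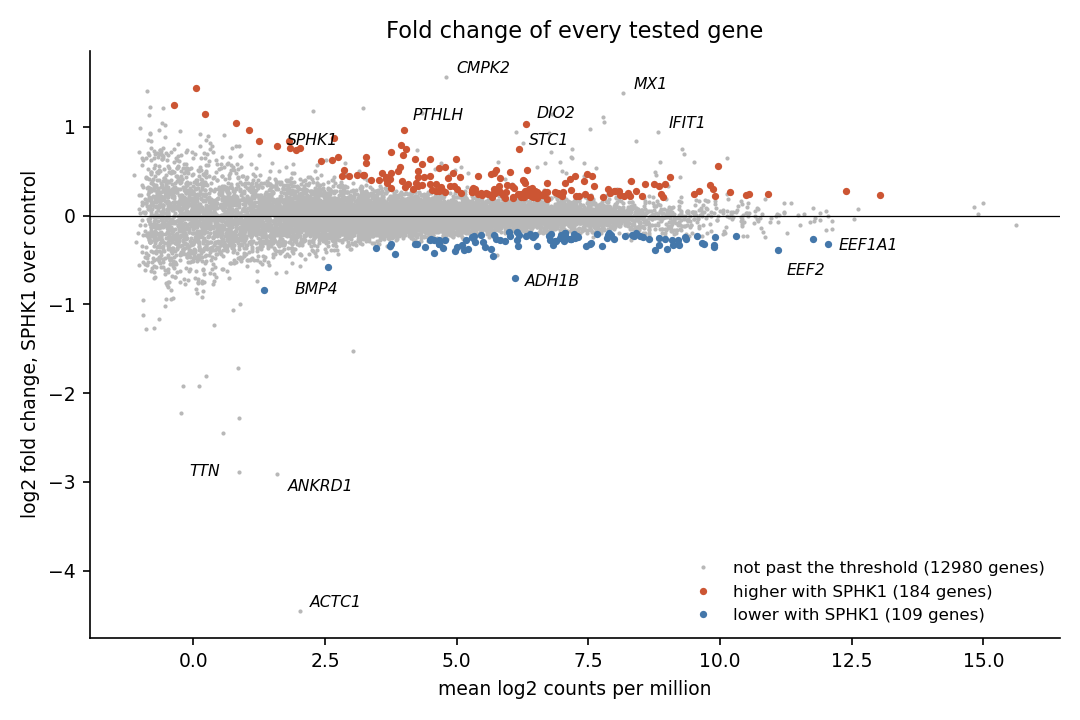
Log2 fold change of SPHK1 over control (vertical axis) against mean log2 CPM (horizontal axis) for every tested gene, with the 184 genes that rose in orange, the 109 that fell in blue and the others in grey. DIO2 (1.03) and PTHLH (0.96) lay above most genes of like abundance, while ACTC1 (-4.46), TTN and ANKRD1, labelled after their values were seen, had large negative fold changes and did not pass the test.

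Of the enzymes that make and break sphingolipids, 33 were measured besides SPHK1. PLPP1, a phosphatase of S1P and related lipids, rose with a log2 fold change of 0.39 ± 0.05 (SE), CERK, the ceramide kinase, fell by 0.33 ± 0.08 (SE), and 31 did not pass. The same counts, 1 higher and 1 lower, held when adjusted over the list alone. CERK did not pass without control replicate 3 or SPHK1 replicates 2 or 3. The list's median was -0.01 on the log2 scale and its mean -0.02, while camera, a set test that compares a list with all other genes, gave the direction as higher with an adjusted p of 0.968. Of 4 measured genes of S1P receptors and export, the receptor gene S1PR3 rose from 91.7 ± 3.81 to 118 ± 7.59 CPM (SD, n = 3). S1PR1 was near 1 CPM, with a log2 fold change of 0.40 ± 0.25 (SE) that did not pass. The set test placed this list higher (adjusted p = 0.0259), and with an estimated correlation the adjusted p was 0.214. Left out in turn, control replicate 1 and SPHK1 replicate 1 each ended that call, with an adjusted p of 0.0592 and 0.104.

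Genes of the type I interferon response had a median log2 fold change of 0.52 over 53 measured members. By the set test the list was higher (adjusted p = 8.4e-58), and with an estimated correlation the adjusted p was 0.214. Of these members, 15 rose and 38 did not pass, and 43 rose when adjusted over the list alone. DDX60L, DDX60 and TRIM21, genes of antiviral defence and ubiquitin ligation, rose by 0.64 ± 0.09, 0.36 ± 0.06 and 0.55 ± 0.08 (log2, SE), and UBE2L6, which conjugates ISG15, by 0.36 ± 0.06. The largest fold changes in the list did not pass, and the libraries of a group differed. The antiviral gene MX1, chosen after its values were seen, had 127, 250 and 99.6 CPM in the controls and 317, 407 and 516 with SPHK1, a log2 fold change of 1.38 ± 0.45 (SE) with an adjusted p of 0.302 in edgeR's test. Relative to the control mean, the mean log2 CPM of the list was -0.09, 0.31 and -0.22 in control replicates 1 to 3 and 0.45, 0.59 and 0.72 in SPHK1 replicates 1 to 3, so control replicate 2 stood above the other controls. With DESeq2 28 members rose, with edgeR's exact test 47, and with scaling by total counts alone 9. Without control replicate 2, 41 members rose. Without control replicates 1 or 3, 5 and 8 members rose, and without SPHK1 replicates 2 or 3, 4 and 5.

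Of 18 measured genes of class I antigen presentation, 4 rose and 14 did not pass, and 7 rose when adjusted over the list alone. Among the genes that rose were HLA-F and 2 chaperones, CALR and PDIA3, of the endoplasmic reticulum that also fold other proteins, which had log2 fold changes of 0.25 ± 0.06 and 0.23 ± 0.06 (SE). HLA genes share reads with close relatives, so their counts are uncertain. Control replicate 2 was again the highest control, at 0.18 against -0.08 and -0.10 in replicates 1 and 3 and 0.23 to 0.28 with SPHK1. The set test gave an adjusted p of 1.33e-08, and the adjusted p was 0.214 with an estimated correlation. Between 0 and 7 members rose when single libraries were left out, with 7 without control replicate 2, 0 without control replicates 1 or 3 or SPHK1 replicate 3, and 1 without SPHK1 replicate 2, and 7 rose by the exact test. Of 14 measured sensors of foreign nucleic acids and their adaptors, TLR3, a receptor of double-stranded RNA, rose by 0.46 ± 0.11 (log2, SE), 13 did not pass, and 2 rose when adjusted over the list alone. This list too was placed higher by the set test (adjusted p = 0.00395), and the adjusted p was 0.322 with an estimated correlation. TLR3 no longer passed in 5 of the 6 fits that left out 1 library, all but the fit without control replicate 2, in which 3 members of the list rose, and by DESeq2 and the exact test 2 and 3 rose.

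**Figure D3:**
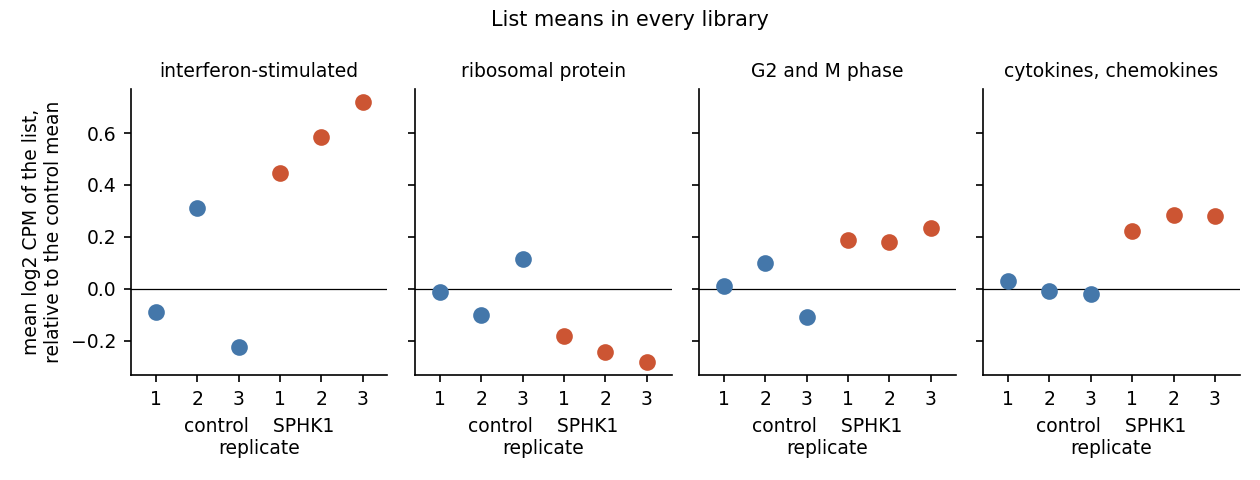
Mean log2 CPM of 4 gene lists relative to the control mean (vertical axis) in each control (blue) and SPHK1 (orange) library. In the interferon list control replicate 2 lay at 0.31 and the SPHK1 libraries at 0.45 to 0.72, while in the cytokine list the controls lay between -0.02 and 0.03 and the SPHK1 libraries between 0.22 and 0.29.

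Of 24 measured cytokine and chemokine genes, 6 rose and 18 did not pass, 19 had a positive and 5 a negative log2 fold change, and 9 rose when adjusted over the list alone. IL6, the gene of interleukin 6, rose from 10.2 ± 0.620 to 16.8 ± 1.56 CPM (SD, n = 3), and the neutrophil-attracting chemokine genes CXCL1 and CXCL6 rose 1.58-fold and 1.39-fold. IL33, which encodes an alarm cytokine stored in the nucleus, rose 1.31-fold from 275 CPM. By the set test the list was higher (adjusted p = 1.83e-08), and the adjusted p was 0.0854 with an estimated correlation. This list was placed higher also by fry, which asks whether the genes of a list move one way on balance (adjusted p = 0.00769). Of 29 measured genes of the NF-kappaB pathway and its targets, PTGS2, the gene of the inducible cyclooxygenase, rose 1.42-fold and 28 did not pass. NFKBIA, which encodes an inhibitor of NF-kappaB, had a log2 fold change of 0.19 ± 0.07 (SE) that did not pass, and the set test did not place the list apart (adjusted p = 0.215). PTGS2 was also the 1 gene of this list past the threshold when adjusted over the list alone.

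Immediate early genes, which respond within minutes to growth signals, had 3 rises among 26 measured members, and 5 when adjusted over the list alone. They were EGR1 (1.26-fold), DUSP6 (1.24-fold) and KLF6 (1.16-fold), and 23 did not pass. Without control replicate 3, 1 member rose. The set test gave an adjusted p of 0.00187, and the adjusted p was 0.214 with an estimated correlation. Of 30 genes of hypoxia and glycolysis, PFKFB4, a regulator of glycolytic flux, rose 1.36-fold and BNIP3, a mitophagy receptor gene, 1.16-fold, and 28 did not pass. Over the list alone 6 rose, the set test gave an adjusted p of 1.36e-05, and the adjusted p was 0.322 with an estimated correlation. In this list 6 members rose without control replicate 2, 0 without control replicate 3, and 1 without control replicate 1 or SPHK1 replicates 1 or 2, while 4 rose by the exact test and 4 with offsets for GC content and length. Of 21 genes of complement and coagulation, the protease inhibitor genes TFPI2 and SERPINE2 rose 1.22-fold and 1.18-fold and 19 did not pass. Over that list alone 2 rose and 1 fell, and the set test gave an adjusted p of 0.0719, with 0.0226 without control replicate 3 and 0.0244 without SPHK1 replicate 2. None of its members rose without control replicate 3, and 1 rose without control replicates 1 or 2 or SPHK1 replicate 1.

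Targets and components of TGF-beta and BMP signalling had 7 rises and 1 fall among 25 measured members, and 9 rises and 1 fall when adjusted over the list alone. INHBA, the gene of the activin A subunit, rose 1.40-fold, TGFB3, a TGF-beta ligand gene, 1.35-fold, SMAD7, an inhibitor of the pathway, 1.28-fold, and ID2, a BMP target gene, 1.19-fold. In camera the list had an adjusted p of 1.83e-07, and the adjusted p was 0.214 with an estimated correlation. By fry the adjusted p was 0.0297. Without control replicates 1 or 3, 3 and 4 members rose, and a fall was called in just 1 of the 6 fits that left out a library, the one without control replicate 2. Among 26 measured growth factors and vasoactive peptides, BMP6 rose, BMP4 and PDGFD, a platelet-derived growth factor gene, fell, and 23 did not pass. PDGFD had a log2 fold change of -0.28 ± 0.05 (SE). Over the list alone 4 rose and 2 fell. The set test placed the list higher (adjusted p = 0.0085), the adjusted p was 0.322 with an estimated correlation, and it was 0.0765 without SPHK1 replicate 3. BMP6 did not pass without control replicate 3 or SPHK1 replicate 3, and BMP4 did not pass without control replicates 2 or 3 or SPHK1 replicates 1 or 3.

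Extracellular matrix and remodelling genes had 6 rises among 44 measured members, and 38 did not pass. Besides MMP1, they included HAS2, a hyaluronan synthase gene that rose from 148 ± 4.98 to 206 ± 8.39 CPM (SD, n = 3), ELN, the elastin gene, at 1.40-fold, and COL4A1, a basement membrane collagen gene, at 1.21-fold. Over the list alone 10 rose and 3 fell. HAS2 shares positions with its antisense RNA HAS2-AS1. The set test placed the list higher (adjusted p = 0.0108), and the adjusted p was 0.545 with an estimated correlation. It was 0.101 without control replicate 1, where 3 members rose, and 0.220 without SPHK1 replicate 1.

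Of 21 measured contractile genes of smooth muscle, 3 fell, none rose and 18 did not pass, with the same counts when adjusted over the list alone. TAGLN fell 1.37-fold, SYNPO2, which encodes an actin-bundling protein, 1.29-fold, and ACTA2, the gene of smooth muscle alpha actin, 1.23-fold. ACTA2 shares positions with FAS. The set test placed the list lower (adjusted p = 0.00668), and the adjusted p was 0.356 with an estimated correlation. The median log2 fold change was -0.05, with 9 members positive and 12 negative, and the list means of the libraries overlapped, at -0.14, 0.09 and 0.05 in control replicates 1 to 3 relative to the control mean and at -0.22, -0.25 and -0.12 in SPHK1 replicates 1 to 3. In the same list DES and CASQ2, muscle genes chosen after their values were seen, had log2 fold changes of -1.53 ± 0.63 and -1.92 ± 1.08 (SE) that did not pass. DES stood at 4.00, 15.8 and 15.8 CPM in control replicates 1 to 3 and at 3.44 to 4.91 with SPHK1. Without control replicates 1, 2 or 3 the list had 4, 2 and 1 falls, without SPHK1 replicates 1 or 2 it had 1, and by the exact test it had 5.

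Of 19 targets of YAP and TAZ, NT5E, an ectoenzyme that makes adenosine, rose 1.35-fold, and AMOTL2 had a log2 fold change of -0.17 ± 0.05 (SE) that did not pass. In this list 18 did not pass, 1 rose when adjusted over the list alone, and the set test gave an adjusted p of 0.418. Of 21 ion channel and calcium handling genes, SLC8A1, the sodium-calcium exchanger gene, rose 1.19-fold, and it did not pass without control replicates 1 or 3 or SPHK1 replicates 2 or 3. KCNMA1, a potassium channel gene, had a log2 fold change of -0.22 ± 0.06 (SE) with an adjusted p of 0.0506 in edgeR's test, so it did not pass. Over that list alone 3 rose and 1 fell. Its median was -0.04 and its mean 0.04, and the set test gave an adjusted p of 0.968.

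Ribosomal protein genes were placed lower with SPHK1 by the set test (adjusted p = 2.49e-28), and the adjusted p was 0.214 with an estimated correlation. Of 29 measured members 13 fell, 16 did not pass and all 29 fell when adjusted over the list alone, with log2 fold changes between -0.35 and -0.13 and a median of -0.23. RPS2 fell 1.25-fold, RPL3 1.24-fold and RPS3 1.21-fold. Many ribosomal protein genes have processed pseudogenes of near-identical sequence, so their counts are uncertain where the counting could split reads. The list mean stood at -0.01, -0.10 and 0.11 in control replicates 1 to 3 relative to the control mean, and at -0.18, -0.24 and -0.28 in SPHK1 replicates 1 to 3. The number that fell was 23 with DESeq2, 22 with scaling by total counts alone and 22 with offsets for GC content and length. Without control replicates 1, 2 or 3 it was 7, 23 and 0, and without SPHK1 replicates 2 or 3 it was 1 and 8. Of 23 genes of the amino acid response driven by ATF4, 3 fell and 20 did not pass, and 4 fell when adjusted over the list alone. As a list they were lower in the set test (adjusted p = 0.000542), the adjusted p was 0.356 with an estimated correlation, and the median log2 fold change was -0.08. TRIB3, a pseudokinase gene, fell 1.27-fold, PHGDH, which starts serine synthesis, 1.18-fold, and SHMT2, of mitochondrial serine metabolism, 1.17-fold. None of its members fell without control replicates 1 or 3, and 1 fell without SPHK1 replicates 2 or 3.

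Genes of the G2 and M phases of the cell cycle had 5 rises among 30 measured members, 25 did not pass, and 21 rose when adjusted over the list alone. CDK1, the mitotic kinase gene, rose 1.22-fold, BUB1, of the spindle checkpoint, 1.21-fold, TOP2A, a DNA topoisomerase gene, 1.21-fold, and TPX2, of spindle assembly, 1.19-fold. As a set, the list had an adjusted p of 9.82e-15, and the adjusted p was 0.214 with an estimated correlation. The list mean was 0.01, 0.10 and -0.11 in control replicates 1 to 3 and 0.18 to 0.23 with SPHK1. Without control replicate 2, 9 members rose, and between 0 and 2 rose in each of the other fits that left out 1 library, and 3 rose with scaling by total counts alone. None of the 30 S phase genes passed, over all genes or over the list alone. PCNA and RFC2, genes of DNA replication, had log2 fold changes of 0.14 ± 0.05 and 0.25 ± 0.10 (SE). The set test placed the S phase list higher (adjusted p = 0.0174), the adjusted p was 0.526 with an estimated correlation, and it was 0.309 without control replicate 3. Of 24 targets of p53, ZMAT3 fell 1.17-fold, FAS had a log2 fold change of 0.22 ± 0.06 (SE) that did not pass, and 23 did not pass. When adjusted over the list alone 1 rose and 1 fell, and the set test gave an adjusted p of 0.10, or 0.0337 without SPHK1 replicate 2. ZMAT3 did not pass without control replicates 1 or 3 or SPHK1 replicate 2.

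Genes of the unfolded protein response of the endoplasmic reticulum had 4 rises among 20, and 7 when adjusted over the list alone. The 4 were the chaperone genes DNAJB11 and CRELD2 (each 1.2-fold), CALR (1.19-fold) and PDIA4 (1.15-fold), and 16 did not pass. Camera gave the list an adjusted p of 0.00395, and the adjusted p was 0.322 with an estimated correlation. None rose without control replicate 3, 1 rose without control replicate 1, and 2 rose without either of SPHK1 replicates 1 and 2. Of 25 genes of cholesterol synthesis and uptake 3 rose and 22 did not pass, and 8 rose when adjusted over the list alone. MSMO1 and SQLE, enzymes of sterol synthesis, rose 1.18-fold and 1.14-fold. Its set test gave an adjusted p of 3.53e-05, and the adjusted p was 0.214 with an estimated correlation. The calls of MSMO1 and SQLE were each lost in at least 4 of the 6 fits that left out 1 library, and 1 member of the list rose with scaling by total counts alone.

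**Figure D4:**
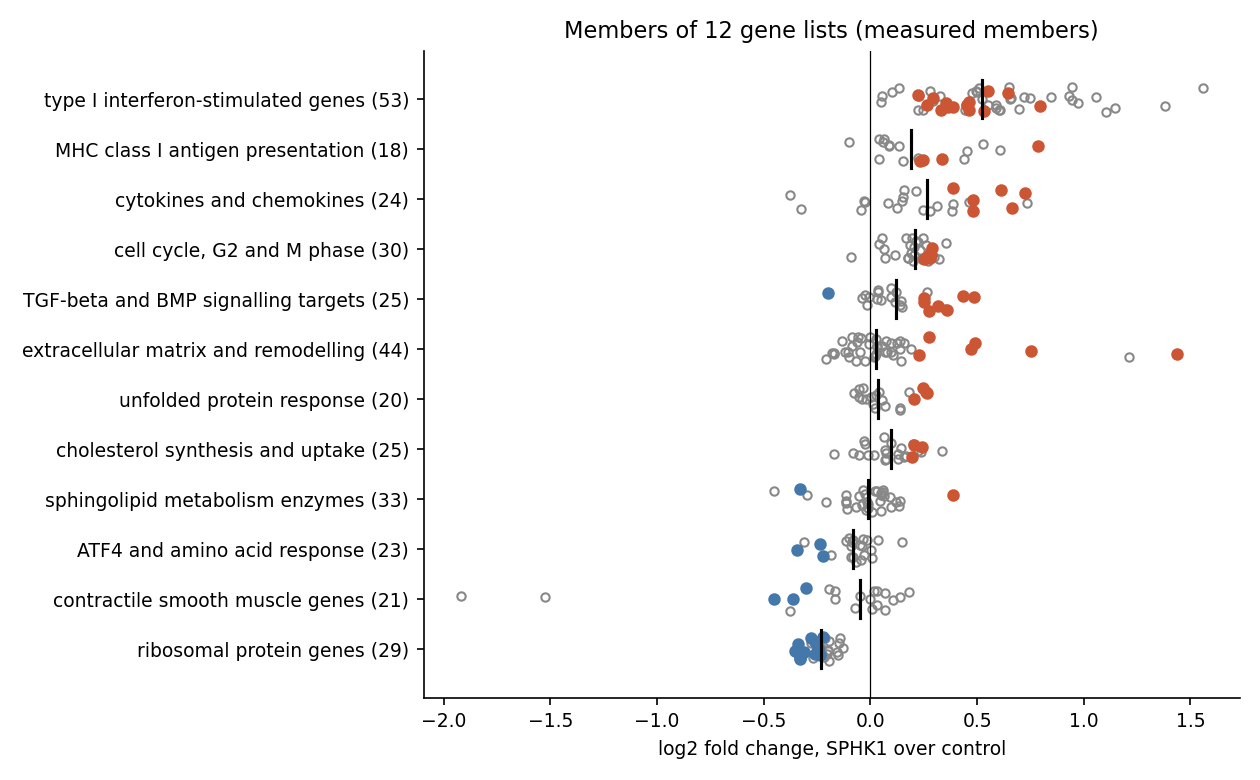
Log2 fold change of SPHK1 over control (horizontal axis) of the measured members of 12 gene lists (vertical axis, number of members in brackets), with members that rose in orange, members that fell in blue, members that did not pass as open circles and the list median as a black bar. The medians ran from -0.23 in the ribosomal protein list to 0.52 in the interferon list.

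None of the members passed over all genes in 4 further groups. The 17 heat shock genes had a set test adjusted p of 0.838, with CRYAB at 0.21 ± 0.08 and DNAJA1 at 0.16 ± 0.06 (log2, SE), a median of -0.0021 and a mean of 0.03. The 9 Notch pathway genes had an adjusted p of 0.965, with JAG1 at -0.17 ± 0.06 and MAML2 at 0.13 ± 0.05. The 20 targets of NRF2, the regulator of the oxidative stress response, had an adjusted p of 0.838, with SLC7A11 at 0.15 ± 0.06 and AKR1C1 at 0.13 ± 0.06. The 25 lysosome and autophagy genes had an adjusted p of 0.982, with CTSL at 0.21 ± 0.06 and CTSZ at 0.13 ± 0.05, a median of -0.03 and a mean of 0.02. Adjusted over each list alone, 0 members passed in the first 3 of these groups and 1 lysosomal gene rose.

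Marker genes of other cell types were examined beside these groups. The measured endothelial markers numbered 8, with EGFL7 at 6.62 ± 1.42 CPM in controls and 7.47 ± 1.35 with SPHK1 (SD, n = 3). PECAM1 had 0.678 ± 0.154 and 0.891 ± 0.216 CPM (SD, n = 3). No endothelial marker passed, and the set test gave an adjusted p of 0.711. No epithelial marker passed among 6, with KRT18 at -0.09 ± 0.05 and CLDN7 at 0.28 ± 0.28 (log2, SE) and a set test adjusted p of 0.979. Of 3 measured leukocyte markers CD68, a lysosomal membrane gene found in cells rich in lysosomes, rose 1.28-fold from 433 ± 18.2 CPM (SD, n = 3), and ITGAX, near 1 CPM, had a log2 fold change of 0.48 ± 0.30 (SE). The set test placed that list higher (adjusted p = 0.0259), and the adjusted p was 0.214 with an estimated correlation. Of 14 fibroblast markers, MFAP5, a microfibril gene, fell 1.26-fold, COL14A1, a collagen gene, 1.16-fold, and 12 did not pass. When adjusted over the list alone 1 leukocyte marker rose and 3 fibroblast markers fell. CD68 did not pass without control replicate 3. Neither fibroblast gene passed without control replicate 3 or SPHK1 replicate 2, and 1 passed without SPHK1 replicates 1 or 3. COL14A1 also did not pass without control replicate 2. The fibroblast list was placed lower (adjusted p = 0.0381), the adjusted p was 0.526 with an estimated correlation, and it was 0.340 without control replicate 3 and 0.172 without SPHK1 replicate 2.

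Over the 31 lists with measured members, 679 genes were measured, 64 of them rose and 26 fell, and camera placed 15 lists higher and 4 lower. None of these 19 calls held with an estimated correlation, where the lowest adjusted p was 0.0854, and 4 held by fry, those of the cytokine, TGF-beta and BMP, immediate early and S1P receptor lists. In the cytokine, S1P receptor and leukocyte lists the estimated correlation was -0.0275, -0.121 and -0.0016, below the preset 0.01. Correlation between genes therefore does not account for the lost camera calls of these lists. The authors' deposited table called 294 higher and 178 lower genes among those tested here, including all 293 of the genes changed here in the same direction and 179 others. The number of changed genes rested on single libraries, with 74 without control replicate 3, 107 without SPHK1 replicate 2, 142 without control replicate 1, 190 without SPHK1 replicate 3 and 445 without control replicate 2. Against a minimum change of 1.2-fold 8 genes passed, DIO2, PTHLH, STC1, ADH1B, IL6, MMP1, P4HA3 and ZCCHC2, the last 2 outside the rule for named genes, and SPHK1 did not pass there (adjusted p = 0.173).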

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

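The alternatives of edgeR's exact test, the newer form of its quasi-likelihood test and offsets for GC content and length were chosen after seeing the data, as were the counts of list members under every alternative. The 293 changed genes became 382 with DESeq2, of which 280 were among the 293, and 298 with limma-voom, of which 286 were. DESeq2 gave no adjusted p for 12 of the 293. Other scalings, filters and the newer form gave 290 to 305, and the offsets gave 385, with 164 lower. At an adjusted p under 0.01, 93 genes changed, 64 higher and 29 lower, and 34 members of the lists passed. Against a minimum change of 1.2-fold 8 genes passed, 7 higher and 1 lower, and 2 members of the lists. The log2 fold change of SPHK1, 0.66, had an adjusted p of 0.173 there, where the test asks whether a change exceeds 1.2-fold. The exact test called 455 genes, 285 higher and 170 lower, and 148 list members, and the cause of the difference was not tested.

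When single libraries were left out in turn, the number of changed genes ranged from 74 without control replicate 3 to 445 without control replicate 2, with 107 without SPHK1 replicate 2, 142 without control replicate 1, 190 without SPHK1 replicate 3 and 242 without SPHK1 replicate 1. Those higher ranged from 55 to 284 and those lower from 19 to 161. The list members past the threshold, 90 in all, ranged from 27 to 143, and the lists past the set test from 17 to 20. SPHK1 kept its call in each of these fits, with a log2 fold change between 0.56 and 0.78. Of 80 named genes that changed, all 80 kept the direction of their log2 fold change under every alternative, although DESeq2 gave 7 of them no adjusted p. The groups did not overlap in any changed gene, so the kept direction was nearly fixed in advance and is little support. Of the 80, 31 passed in each fit that left out 1 library. With fewer libraries the tests also have less power, so a lost call alone does not show a smaller change. Each of these fits lost 1 library, yet the counts ran from 74 to 445, so they also depend on which library was left out.

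Of the 19 lists past the set test, 0 passed with an estimated correlation, 4 by fry for movement one way and 17 by fry for change in either direction, which called 24 lists. The offsets, the scaling by total counts alone and the replicate block on the title numbers each kept all 19. The replicate numbers did not pair the libraries, as the correlations of deviations from the group means were -0.167, 0.0097 and -0.0058 for title numbers 1 to 3, and -0.167 and -0.051 for numbers 1 and 3 of the sample descriptions, which number the controls differently. As a hint from the data, not the design, 0 of the 6 libraries correlated best with the library of the same title number in the other group. With the title numbers as a replicate block 197 genes changed, 131 higher and 66 lower, and with the description numbers as a replicate block 111 changed, 89 higher and 22 lower, 58 of them among the 293. Under these 2 blocks 8 and 0 ribosomal protein genes fell, against 13, and 12 and 31 interferon-stimulated genes rose, against 15. Description number 4 is held by control replicate 3 alone and number 2 by SPHK1 replicate 2 alone. Under that block these libraries add nothing to the comparison of the groups, so its counts also reflect their loss. At this depth and spread, part of the simulated changes of 1.3-fold and 1.5-fold was missed, with 64.9% and 76.1% recovered.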

Other observations

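The tests on translation genes, on well-to-well differences, on plasmid preparations, on GC content and length, on uncounted plasmid reads and on other splits of the libraries were chosen after the results were seen, and all genes named in this section apart from SPHK1 and PTGS2 were chosen after their values were seen. The tests on wrong labels and on matched genes also address patterns that had already been seen in the results. PTGS2, TGFBI and MMP3 belong to lists fixed before the data were examined, and no list was fixed or tested for the other themes in this paragraph. PTGS1, the constitutive cyclooxygenase gene, and PTGES, a prostaglandin E synthase gene, rose by 0.23 ± 0.05 and 0.30 ± 0.06 (log2, SE), and PTGS2 of the NF-kappaB list by 0.50 ± 0.07. The butyrophilin genes BTN3A1, BTN3A2 and BTN3A3 rose by 0.24 ± 0.05, 0.35 ± 0.08 and 0.30 ± 0.06, although they are close copies and can share reads. The integrin genes ITGA2, ITGA5 and ITGB3 rose by 0.24 ± 0.05, 0.34 ± 0.06 and 0.27 ± 0.05, and TGFBI, a matrix protein that binds integrins, by 0.28 ± 0.05 at a level of 4833 CPM in controls. Genes of guidance cues and their receptors went both ways, as SEMA3A and NRP2 rose by 0.28 ± 0.06 and 0.39 ± 0.09, while SLIT2, SLIT3 and SEMA5A had log2 fold changes of -0.30 ± 0.06, -0.22 ± 0.05 and -0.26 ± 0.05 and fell. MMP3, the stromelysin gene of the extracellular matrix list, had the largest fold change among all genes that passed, at 1.44 ± 0.31, from 0.516 CPM in controls.

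The 3 striated muscle genes ACTC1, TTN and ANKRD1 had more counts in control replicates 2 and 3 than in the other 4 libraries. ACTC1, the cardiac alpha actin gene, had 462 and 203 counts in control replicates 2 and 3, but 2 in control replicate 1 and 8, 1 and 20 in SPHK1 replicates 1 to 3. TTN, the titin gene, had 12, 154 and 106 counts in control replicates 1 to 3 and 8, 11 and 16 with SPHK1, and ANKRD1 had 13, 225 and 220 against 14, 11 and 33. Not every such gene did so, as CASQ2 had 18, 104 and 18 counts in control replicates 1 to 3 and 13, 5 and 18 with SPHK1. In edgeR's quasi-likelihood test the adjusted p of ACTC1, TTN and ANKRD1 were 0.411, 0.367 and 0.403, and the controls disagreed. In the authors' deposited table these 3 genes have log2 fold changes of -4.48, -2.88 and -2.91 with adjusted p of 0.000778, 6.15e-05 and 0.000313, and of that table's 10 largest falls 8 pass there and 0 passed here, where 109 genes fell, 1840 genes had an unadjusted p under 0.05 and DESeq2 called 382 genes. The antiviral gene MX1 has an adjusted p of 2.26e-06 in the authors' deposited table and 0.302 in edgeR's test here. The small cytoplasmic RNA RN7SL1 stood at 27.8 CPM in SPHK1 replicate 2 and at 1.71 to 11.7 in the other 5 libraries.

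Interferon-stimulated genes were higher with SPHK1 as a list, although 38 of 53 members did not pass and the set test's adjusted p was 0.214 with an estimated correlation, and control replicate 2 lay between the other controls and the SPHK1 libraries. A wrong label or a mixed sample in control replicate 2 stays open: over the 403 genes other than SPHK1 and outside the list that changed in the fit without it, its median position was 0.486 (quartiles 0.298 and 0.681) on a scale from 0, the other controls, to 1, the SPHK1 libraries, where the same measure was 0.0852 and -0.165 for the other controls and 0.706 to 1.04 for the SPHK1 libraries. Wells that differ in their interferon response whatever the plasmid cannot be told apart from the plasmid's effect, since the gap between the groups in the list's mean log2 CPM was 0.134 and the range of the controls 0.537. Plasmid preparations or doses that differ between the groups, a possible explanation because plasmid DNA can itself set off this response, also stay open, as 0 libraries of untransfected cells or of a second preparation were named in the labels. An effect of SPHK1, which the design names, remains among the open explanations and was not tested apart from these.

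Ribosomal protein genes were lower with SPHK1 as a list, although the set test's adjusted p was 0.214 with an estimated correlation and 16 of 29 members did not pass. A bias with GC content and transcript length as the whole cause is argued against, since the list's median log2 fold change was -0.226 after each library's trend was removed and -0.23 before, with an SD of 0.0629 over the members and a set test adjusted p of 8.14e-29 at the preset correlation. A shift of all short and abundant transcripts is argued against by 54 genes matched to the list on abundance, length and GC content, whose median was -0.000268 (95% bootstrap interval -0.0179 to 0.0206). The match was not exact, with a median exonic length of 1348 bases against 1044 in the list and a mean log2 CPM of 8.42 against 8.76. The interval was drawn over genes, not libraries, so it leaves out the spread between libraries. The hypothesis that mRNAs of the translation machinery may be lower as a class was drawn from these data, which therefore cannot establish it. The values go with it, with a median of -0.157 over 48 other ribosomal protein genes, 46 of them negative and 7 that fell, and of -0.205 over 26 translation factor and related genes, all 26 negative and 10 that fell, among them EEF1A1, EEF1G, EIF4B and EIF3L. Both lists had an adjusted p of 1.01e-20 in camera and 0.0785 with an estimated correlation, adjusted over these lists alone. Some members had been seen before the lists were written, and reads shared with pseudogenes were not tested. The 0.214 of the ribosomal protein list was adjusted over all fixed lists with measured members, so it cannot be compared with 0.0785. Before adjustment, camera with an estimated correlation gave the ribosomal protein list p = 0.0532.

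SPHK1 mRNA rose 1.58-fold and ranked 100 among the tested genes by fold change. A wrong label on an over-expression library is argued against, because over the genes that changed without it each SPHK1 library had a median position nearer to the other SPHK1 libraries than to the controls, the lowest at 0.706 with a lower quartile of 0.55. Reads of the transfected construct that were not counted on SPHK1, for instance because its sequence differs from the gene's, could hide a larger rise, and 0 tables of exon or construct counts were analysed here, so this stays open. A small share of transfected cells would also give a low mean over all cells, and it was not tested.

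Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 293 genes in edgeR's quasi-likelihood test and the highest of the others 0, and 1 of the 10 splits, the real one, gave as many. Every other split mixes libraries of both groups, so a real difference between the groups would add to the spread within each side and lower the count. The 0 is therefore not the count to be had without any difference. At an unadjusted p under 0.05 the real split gave 1840 genes and the others 198 to 1375, with no other tool run on the splits. For the lists past the set test the real split gave 19 and the highest of the others 14, and 1 of the 10 splits, again the real one, gave as many.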
